A study of Mus musculus with 2 samples.

How the data were processed

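The samples were total RNA from liver of Twist2-Cre control and Twist2-Cre/A20fl/fl (CKO) mice at 24 weeks, 1 sample each, grouped by the genotype in the labels. Per the labels' protocols, RNA was amplified with an amino allyl aRNA kit, coupled to Cy5 and fragmented after TORAY's protocol. The scanner files hold, per the file headers, the median intensity of each spot and of its local background in a single colour, scanned at 3 gains that were related by least-squares lines; the scanner software and the array's name are not given in the sources used here. The deposited value table also holds intensity on a linear scale that is not centred on genes. How it was made is not stated; tested on the values, each entry is the spot intensity minus the blank spots' mean (5% trimmed at each end), times a factor per array (0.859 control, 0.825 CKO), rounded to whole numbers, to within 1.54 on the control array and 0.514 on the CKO array. Its median is 25 on both arrays, and it lists 17910 (76.3%) and 17979 (76.6%) of the gene probes, those above the trimmed blank mean plus 2 SD. Each column holds the levels of 1 sample, so its direction is not in question.

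Each array had 27456 spots, including 384 blank spots and 3454 positions without a probe. Blank spots had a mean of 67.2 (SD 1.17) on the control array and 69.3 (SD 1.45) on the CKO array, while gene spots had medians of 81.1 and 84.0, so many genes lie close to background and their ratios are imprecise. No spot was at the scanner's upper limit. Flagged spots, 4 on the control array and 0 on the CKO array, were left out. The 2 kinds of positive control spots, 24 of each per array, varied by 0.175 and 0.197 (SD of log2) on the control array and 0.149 and 0.140 on the CKO array, which measures spot-to-spot error only.

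Intensities were background-corrected with normexp (limma 3.58.1 in R 4.3.3) with an offset of 50, control spots were then left out, and the arrays were quantile-normalized and put on the log2 scale. The design laid down before the data were examined used the local background column. That column was replaced by the mean of the blank spots, a decision taken from the column itself before any ratio was seen: it correlated with the spot's own log2 signal across spots (r = 0.989 control, 0.973 CKO) and, over gene spots brighter than 1000, its median share of the spot's signal was 0.752 and 0.582. It was 57.6 and 61.3 around blank spots but 1583 and 1267 around bright ones, so it rose with the spot's own signal. The setting as first laid down was kept as an added alternative. The offset shrinks ratios of dim genes, and differences near background are therefore larger in the deposited intensities than in the normalized ratios.

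Probes were named from the platform annotation: 20690 of 23473 gene probes had 1 symbol, 0 had several, and 2783 had none and are not named. Entrez IDs matched a RefSeq table (GRCm38.p6), used for names only, for 20556 probes, and 0 symbols needed updating. A gene's value was the mean log2 of its probes (1283 of 19321 genes had at least 2); in 1 gene the probes disagreed in sign with 1 probe past 2-fold. A probe was above background when its spot exceeded the mean plus 2 SD of the blank spots (69.5 control, 72.2 CKO), and a gene when any of its probes did. Genes above background on 1 array only were given as "at least" folds, the brighter normalized value against the higher of the dim value and the lowest normalized signal above background on that array.

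With 1 array per genotype no test and no p-value was possible. Genes were counted past a fixed size, 2-fold. For each of 43 gene lists written before the data were examined (pathways, liver zones, cell type markers including those of other tissues, and neighbours of Tnfaip3), the median ratio of the members above background on both arrays was set against 10000 random lists of the same size matched on mean level in 20 classes. A list with at least 5 such members was said to stand apart when its median fell outside the middle 95% of them. This describes these 2 arrays only; random lists ignore that genes of a pathway vary together, so lists stand apart more readily than the chance share implies, and 26 did. Named genes, also fixed in advance, were Tnfaip3; the 15 largest ratios in each direction among genes at or above the median level that were past 2-fold under quantile and under median scaling (10 qualified on the lower side); the 5 largest bounds in each direction; and up to 4 members of each list with the largest absolute ratios, whatever their size. The sex-linked genes of the Results and Socs3 in the closing section fall outside this rule and were chosen after their values were seen. The clock genes that only the closing section names also fall outside it; they belong to a test whose genes were fixed before its result was seen.

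The procedure was tested on simulated arrays with known changes (14073 genes). With the offset, 32 of 50 genes raised 4-fold and 1 of 50 raised 2-fold passed 2-fold, with median ratios of 1.40 and 0.46; 18 of 37 genes lowered 4-fold and 3 of 42 lowered 2-fold passed, and 0 of 13894 unchanged genes did. With plain subtraction, 50 of 50 and 33 of 50 raised genes, 36 of 37 and 17 of 42 lowered genes and 71 of 13893 unchanged genes passed. Of 200 random lists of unchanged genes 7 (3.5%) stood apart, a small share that follows by construction because they were themselves drawn at random. The simulated array was the control array with independent spot noise. It held no difference between animals and no shared variation of genes, so these shares do not measure false calls between 2 livers. Plain subtraction took the blank mean from each spot, with no normexp and no offset, and was followed by the same quantile normalization. Alternatives covered scaling, background, offset, source of values, filter, probe summary, list summary and matching of random lists. Calculations and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.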

Results

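Gene expression was measured in whole liver of 24-week-old mice on 2 single-colour microarrays, 1 for the Twist2-Cre control and 1 for the Twist2-Cre/A20fl/fl genotype, here called CKO. The number of animals behind each RNA is not given in the sources used here. Twist2-Cre recombines floxed alleles in mesenchymal lineages, and A20, encoded by Tnfaip3, is a ubiquitin-editing enzyme that restrains NF-kB signalling. The comparison asks which liver transcripts differ in level between these genotypes. Of 23473 gene probes, 17314 (73.8%) gave signal above background on the control array and 17282 (73.6%) on the CKO array. With 1 array per genotype there was no test, no error across animals and no replicate check, and the number of arrays limits the precision. All ratios are log2 of CKO over control on a normalized scale that shrinks the differences of dim genes, so deposited intensities are given beside the leading values. Genes are ranked on this scale, and other scales can order them differently. As a guide to size only, genes of similar level had a spread of ratios of 0.03 in the dimmest of 20 level classes and of up to 0.21 in brighter ones, and probes of 1 gene differed by 0.13 (SD, 716 genes).

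Tnfaip3 itself had a similar level on both arrays. Its log2 level was 6.68 in the control and 6.62 in the CKO liver, a ratio of -0.07 that lies within the spread of genes at its level (0.13), and its deposited intensities were 41 and 38. The part of the transcript that the probe reads was not known, and a probe outside the deleted part checks nothing. Whole liver also holds cells outside the mesenchymal lineages, whose transcript the deletion would leave intact. This value therefore neither bears out nor contradicts the label. Twist2 had a ratio of -0.37, with deposited intensities of 239 and 172. The 19 measured genes near Tnfaip3 on chromosome 10 had a median ratio of 0.00 that lay within the random lists, with 9 higher and 10 lower. The sex-linked genes, read outside the rule for named genes, were Xist (0.09, deposited intensity 132.5 and 142.5) and the Y-linked Kdm5d (-0.08, 33 and 29) and Eif2s3y (0.00). Eif2s3y was close to background (6 and 6), so its ratio carries little weight, and no sex is read from these values.

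On the offset scale most transcripts were at similar levels, and the larger differences were mainly on the higher side in the CKO liver. Among 14143 genes above background on both arrays, 90 (0.636%) were at least 2-fold higher and 11 (0.0778%) at least 2-fold lower in the CKO liver. On this scale 13842 (97.9%) lay within 1.5-fold. Simulated genes raised 2-fold had a median ratio of 0.46 on it, itself within 1.5-fold, so true 2-fold differences can lie inside that share. At 4-fold, 18 genes were higher and 0 lower. Of the genes past 2-fold, 48 of the higher and 3 of the lower ones belong to at least 1 of the 43 gene lists fixed in advance. The counts depended strongly on the handling of background and offset, with 608 genes higher and 44 lower with plain subtraction of the blank mean, which uses neither normexp nor an offset, and 181 and 19 with an offset of 16. In the deposited values, which also differ in scaling, 557 were higher and 158 lower. The median ratio over all genes used was 0.077 with plain subtraction, -0.042 in the deposited values and -0.017 on the offset scale. Simulated unchanged genes had a median of 0.088 with plain subtraction, so its counts and list medians lean to the higher side. Against the local background column, the setting first laid down, 432 were higher and 196 lower, and 33 of the 90 and 7 of the 11 genes were among them.

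**Figure D1:**
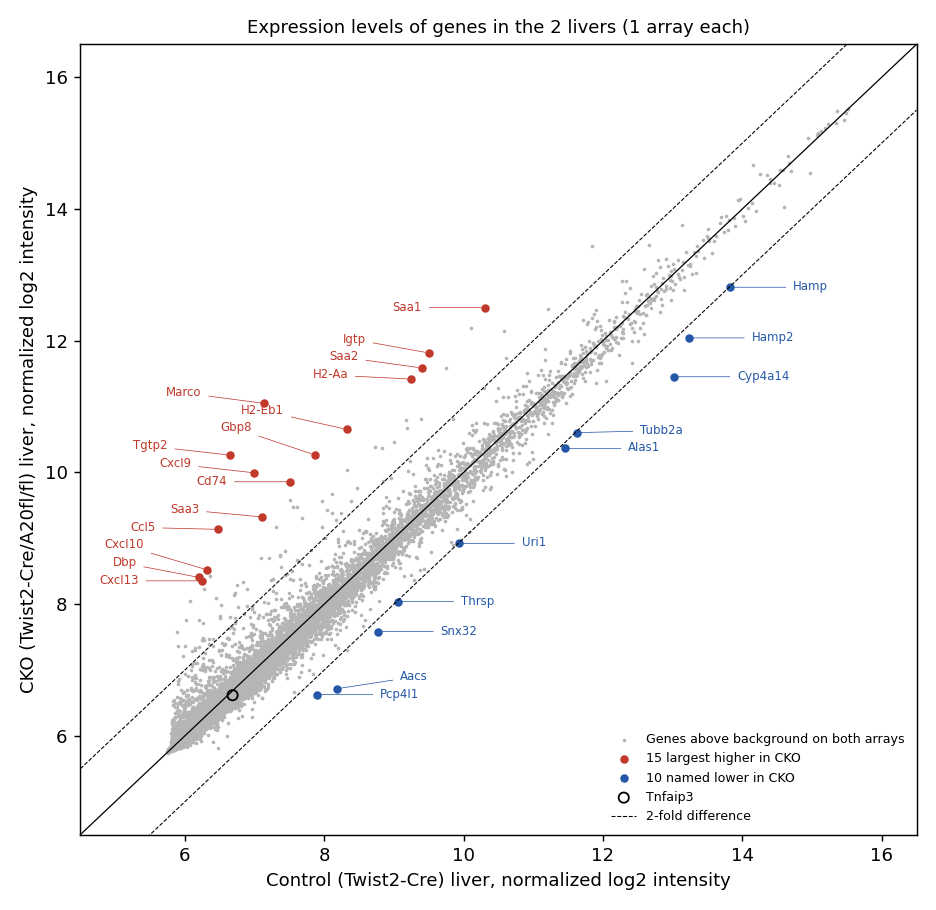
Normalized log2 intensity of each gene above background on both arrays, with the control liver on the horizontal axis and the CKO liver on the vertical axis; 1 point is 1 gene, and dashed lines mark a 2-fold difference. The 15 named higher genes (red) reach a log2 ratio of 3.91 at Marco, the 10 named lower genes (blue) reach -1.57 at Cyp4a14, and Tnfaip3 (circle) lies near the line of equal levels.

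Genes induced by interferon-gamma and genes of antigen presentation were higher in the CKO liver as groups. All 17 measured interferon-gamma-induced genes were higher, 12 of them by at least 2-fold, with a median ratio of 1.39 that exceeded all 10000 random lists matched on level. They included the immunity-related GTPase Igtp (2.32, deposited intensity 582 in the control and 2936 in the CKO liver), the guanylate-binding proteins Gbp2 (2.06) and Gbp6 (1.96), and the immunoproteasome subunit Psmb9 (1.70). Of 9 measured genes of MHC class II presentation 8 were higher, 7 of them by at least 2-fold, with a median of 1.64, again above all random lists. Their largest ratios were those of the invariant chain Cd74 (2.35, 108 and 721), H2-Eb1 (2.33, 226 and 1281), H2-Aa (2.17, 471 and 2209) and H2-Ab1 (2.07, 109 and 584). All 11 measured genes of MHC class I presentation were higher with none past 2-fold on the offset scale (median 0.52). H2-K1 (0.79), the peptide transporter Tap1 (0.73, 14 and 54), H2-Q6 (0.70) and H2-Q7 (0.60) led this list. Type I interferon-stimulated genes had a smaller median of 0.34, with 17 of 20 higher and none at 2-fold on that scale. Among them were Xaf1 (deposited intensity 103 and 250), Usp18 (0.83, 34 and 96), Rsad2 (0.62) and Irf7 (0.62, 36 and 79). Outside the lists, the interferon-inducible GTPases Tgtp2 (3.61, 40 and 967) and Gbp8 (2.41, 152 and 969) ranked among the 15 largest ratios. Members of these GTPase and MHC families are close in sequence, so the split between single members is uncertain. With plain subtraction the 4 medians were 2.08, 2.35, 0.77 and 0.64 in the order given. The MHC class I and type I interferon lists no longer stood apart against the local background column. There H2-Q7 had the opposite sign (-0.06), H2-K1 was at 4.53, and Gbp2 (0.90), Gbp6 (0.31) and H2-Eb1 (0.80) were below 2-fold.

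Chemokines, acute phase proteins and NF-kB targets were higher as groups. Of 19 measured chemokines 16 were higher, 6 of them by at least 2-fold, with a median of 0.64 above all random lists. The interferon-inducible Cxcl9 had deposited intensities of 62 and 794, and the T cell attractant Ccl5 was 6.32-fold higher (30 and 418), Cxcl10 4.62-fold (22 and 262) and the B cell attractant Cxcl13 4.32-fold (19 and 230). Complement and acute phase genes had a median of 0.30, above all random lists, with 7 of 27 at least 2-fold higher and 1, Hamp, 2-fold lower. The serum amyloid genes Saa3 (2.21), Saa1 (2.20, 1047 and 4707) and Saa2 (2.19, 530 and 2457) led this list with the metallothionein Mt2 (2.07, 904 and 3691); Saa1 and Saa2 are near copies whose signals a probe may share. Of 21 NF-kB targets 19 were higher, with a median of 0.13 above all random lists and 1 past 2-fold on the offset scale. That gene was the adhesion molecule Vcam1 (1.87, 119 and 546), followed by Il1b (0.96, 26 and 93), the NF-kB inhibitor Nfkbia (0.62) and the A20-binding protein Tnip1 (0.53). Cell death genes had a median of 0.21, above all random lists, with 11 of 16 higher and none past 2-fold on the offset scale. The necroptosis effector Mlkl (0.72, deposited intensity 22 and 66), Fas (0.55, 125 and 203), Casp1 (0.47, 21 and 46) and Casp4 (0.43, 9 and 28) had the largest ratios. Genes of ubiquitin editing and TNF receptor signalling had a median of 0.04 within the random lists, with Tnip1 (0.53), Tax1bp1 (0.16), Traf2 (0.16) and Rnf31 (0.16) as largest. With plain subtraction the medians of the chemokine, acute phase, NF-kB and cell death lists were 1.78, 0.44, 0.71 and 0.47, which reverses the order of the last 3. Against the local background column the NF-kB and cell death lists no longer stood apart, the latter with a median of -0.005. There Fas had the opposite sign (-0.38), and Cxcl9 (0.58), Ccl5 (0.20) and Cxcl10 (0.91) were below 2-fold, while Nfkbia (2.10) and Saa1 (4.11) had larger ratios.

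Markers of macrophages and monocytes were higher in the CKO liver. All 15 measured markers of Kupffer cells and macrophages were higher, 6 by at least 2-fold, with a median of 0.80 above all random lists. The scavenger receptor Marco had a ratio of 3.91 (deposited intensity 74 and 1707), and the complement components C1qa (1.60) and C1qb (456 and 1300) and the macrophage protein Cd5l (1.55) followed. All 13 measured markers of monocytes and recruited macrophages were higher, 3 by at least 2-fold, with a median of 0.48 above all random lists. These were lysozyme Lyz2 (1.84, 695 and 2437), galectin Lgals3 (1.43) and Plac8 (1.19), with Ms4a7 next (0.97); Chil3, above background on the CKO array only, was at least 1.51-fold higher. With plain subtraction the median of the monocyte list was 1.76 and that of the Kupffer cell list 1.35. C1qa (0.75) and C1qb (0.83) were below 2-fold against the local background column.

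Lymphocyte and granulocyte markers were dim, with smaller ratios on the offset scale. T cell markers had a median of 0.06, above 99.6% of random lists, with 8 of 11 higher and none past 2-fold; the largest were the CD8 chains Cd8b1 (0.71, deposited intensity 3 and 34) and Cd8a (0.49), Cd3d (0.39, 19 and 39) and Cd2 (0.33). Of 8 NK and cytotoxic cell markers 7 were higher, with a median of 0.24 above all random lists and 1 past 2-fold, Ccl5, which is also a chemokine of the list above. The granzymes Gzma (0.69, 5 and 36) and Gzmb (0.63, 24 and 62) and the receptor Klrd1 (0.28) were the next largest, and Nkg7, above background on the CKO array only, was at least 1.49-fold higher. With plain subtraction the T cell, NK and neutrophil medians were 0.78, 1.56 and 0.78. Neutrophil markers had a median of 0.04, above 98.0% of random lists, with 8 of 10 higher; Lcn2, also an acute phase gene, was 3.80-fold higher, and S100a9 (0.67), S100a8 (0.45) and Csf3r (0.40) were smaller. B cell and plasma cell markers (median 0.02 over 7 genes; Cd79b 0.20, Cd22 -0.12, Mzb1 0.04, Fcrla 0.04) and dendritic cell markers (median 0.02 over 8 genes; Bst2 0.53, Batf3 0.29, Itgae -0.18, Clec10a 0.12) lay within the random lists; with no filter on dim genes the dendritic cell list stood apart as higher. Itgae had the opposite sign with plain subtraction (0.35), in the deposited values and against the local background column, and so did Bst2 (-0.52), Batf3, Klrd1 and Cd79b in the last of these settings. The neutrophil list no longer stood apart under median scaling, cyclic loess or random lists not matched on level, and neither it nor the NK list did against the local background column. Fewer than 5 members of the T cell, NK and neutrophil lists lay at or above the median level of all genes, so none was called there.

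Fibrillar matrix genes were higher, while markers of stellate cells were near equal and those of endothelial and bile duct cells lower. The list of myofibroblast and fibrillar matrix genes had 17 of 20 members higher and none past 2-fold, with a median of 0.20 above all random lists. The intermediate filament Vim (0.79, deposited intensity 204 and 377) and the collagens Col1a2 (0.62, 59 and 114), Col3a1 (0.57) and Col6a1 (0.46) had the largest ratios, and the list's median was 0.79 with plain subtraction. Stellate cell markers had a median of -0.01 within the random lists, with 5 of 14 higher and ratios of -0.29 for Ecm1, 0.09 for Pth1r, -0.09 for Reln and 0.06 for Pdgfrb. Portal fibroblast and mesenchymal markers had a median of -0.09, at percentile 1.59 of random lists, with 10 of 15 lower, among them Dcn (-0.52) and Msln (-0.25), and Thy1 higher (0.26). Sinusoidal and vascular endothelial markers were lower in 15 of 17 genes, with a median of -0.16 below all random lists; Oit3 (-0.64, 200 and 112), Clec4g (-0.48), the VEGF receptor Kdr (-0.43) and Ptprb (-0.35) differed most. Of 13 cholangiocyte and ductular markers 12 were lower, with a median of -0.14 below nearly all random lists, from Krt19 (-0.33), Onecut1 (-0.24) and Krt7 (-0.20) to the 1 higher gene, Prom1 (0.30). No member of these lower lists differed by 2-fold on the offset scale. In the deposited values, of their named members, Thy1 (12 and 41) was past 2-fold higher and Krt19 (27 and 13) past 2-fold lower. Against the local background column the portal fibroblast, endothelial and cholangiocyte lists no longer stood apart, and Ecm1 (1.67), Prom1 (-0.12) and Onecut1 (0.03) had the opposite sign. The portal fibroblast call also ended with plain subtraction, with an offset of 16, in the deposited values, with the brightest probe and with the mean in place of the median. Among genes at or above the median level, the portal fibroblast and cholangiocyte calls ended.

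Markers of hepatocytes as a whole were near equal between the livers. Their median was 0.00 within the random lists, with 9 higher, 9 lower and 1 equal of 19, and with Tat (-0.42), Arg1 (-0.39), Ass1 (-0.22) and Hnf4a (0.33) as largest. Pericentral genes had a median of 0.13, above 99.9% of random lists, with 11 of 14 higher; the ammonium transporter Rhbg was 2.28-fold higher, Oat had a ratio of 0.63, glutamine synthetase Glul 0.58 and Slc1a2 0.40. Rhbg had the opposite sign, -0.93, against the local background column, where the pericentral list no longer stood apart. Periportal genes had a median of -0.01 within the random lists, with Pck1 (0.57), Ctsc (0.55), Uroc1 (-0.37) and Aldh1b1 (0.26) as largest; Ctsc (-0.08) and Uroc1 (0.20) had the opposite sign against the local background column.

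Genes of fatty acid synthesis were lower in the CKO liver as a group. Of 18 measured genes 16 were lower, 1 by at least 2-fold, with a median of -0.22 below all random lists. The lipogenic regulator Thrsp was 2.03-fold lower (deposited intensity 412 and 174), fatty acid synthase Fasn had a ratio of -0.95 (744 and 351), malic enzyme Me1 -0.79 and the desaturase Scd1 -0.56 (21634 and 13480). This list no longer stood apart against the local background column, at percentile 5.17, though Thrsp (-1.17), Fasn (-1.69), Scd1 (-1.01) and Me1 (-0.41) stayed lower there. The other metabolic lists, and ribosomal proteins, lay within the matched random lists, with members on both sides. The median was -0.04 for cholesterol synthesis (Mvd -0.60, Insig1 -0.39, Stard4 -0.32, Sc5d 0.31) and 0.03 for bile acid synthesis and transport (Nr0b2 -0.92, Abcb4 0.58, Cyp7b1 0.49, Baat -0.37). Genes of PPAR-alpha and fatty acid oxidation had a median of 0.01, with the fatty acid hydroxylase Cyp4a14 2.97-fold lower (7065 and 2252) and the lipid droplet protein Plin2 (0.79), the carnitine transferase Cpt1a (0.44) and Cyp4a31 (0.37) higher. Gluconeogenesis and amino acid catabolism had a median of -0.04 (Pck1 0.57, Tat -0.42, G6pc -0.42, Fbp1 0.32). Xenobiotic metabolism had a median of 0.00, with the cytochromes Cyp3a11 (0.99) and Cyp2c55 (0.82) higher, Ces2a (-0.45) lower and Cyp2c50 at 0.31. Mitochondrial respiration had a median of -0.07 (Uqcrc2 -0.40, Cyc1 -0.27, Ndufa9 -0.24, Sdha -0.23), and ribosomal proteins had one of 0.02 (Rpl32 -0.25, Rps15 -0.24, Rpl3 0.23, Rpl8 -0.19). The gluconeogenesis and ribosomal lists stood apart as higher against the local background column, at percentiles 98.0 and 99.96. There Cyp3a11 (-0.14), Cpt1a (-0.15), Stard4 (0.15), Uqcrc2 (0.02), Cyc1 (3.20), Rpl3 (-0.42) and Rpl8 (2.83) had the opposite sign. With random lists not matched on level, bile acid genes stood apart as higher and mitochondrial genes as lower.

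Cell cycle genes were higher, mostly from low levels. Of 18 measured genes 15 were higher, 2 by at least 2-fold, with a median of 0.27 above all random lists. The anaphase activator Cdc20 was 3.35-fold higher (deposited intensity 9 and 136) and the kinase Cdk1 2.22-fold (17 and 93), with Birc5 (0.98) and Aurka (0.60) next. Top2a, Ccna2 and Cdca3, above background on the CKO array only, were at least 1.72-fold, 1.57-fold and 1.46-fold higher. With plain subtraction the median of the list was 1.23. Cdc20 (0.998) and Cdk1 (0.41) were below 2-fold against the local background column, where Birc5 had the opposite sign (-0.20). Genes of fetal liver and liver tumours lay within the random lists (median 0.02 over 7 genes). Ly6d was at 0.79, Golm1 at 0.10, Sox4 at -0.04 and Scd2 at 0.04. Another 7 of the 15 listed genes were above background on neither array, and 1 on the CKO array only. With the mean in place of the median this list stood apart as higher, at percentile 98.3.

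Stress lists gave mixed values. Oxidative stress and NRF2 target genes had a median of 0.14, above 99.9% of random lists, with 11 of 16 higher; haem oxygenase Hmox1 was 2.21-fold higher, and Ugdh (0.61), Ephx1 (0.30) and Taldo1 (0.25) were smaller. Genes of the unfolded protein and integrated stress response had a median of -0.13, at percentile 1.20 of random lists, with 13 of 19 lower (Manf -0.33, Dnajb9 -0.28, Pdia4 -0.26) and Asns at 0.40. Against the local background column this median was 0.05, Manf (0.33), Pdia4 (0.28) and Ephx1 (-0.01) had the opposite sign, Hmox1 (0.79) was below 2-fold, and the unfolded protein list also no longer stood apart with plain subtraction, with an offset of 16, in the deposited values or with the mean. Immediate early and heat shock genes went both ways: 10 of 18 were higher, with a median of 0.07 above 99.6% of random lists. Gadd45g was 2.98-fold higher, and the chaperones Dnajb1 (-0.89), Hsp90aa1 (-0.55) and Hspa8 (-0.51) were lower. The median of this list was -0.07 among genes at or above the median level and -0.02 against the local background column, and it did not stand apart there or with the mean.

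Clock genes differed in both directions. The list had a median of 0.07, above 99.2% of random lists, with 9 of 15 higher and 6 lower, and no longer stood apart with plain subtraction, with an offset of 16, in the deposited values, against the local background column or among genes at or above the median level. The clock output factor Dbp was 4.59-fold higher (deposited intensity 17 and 239), the repressors Nr1d2 and Nr1d1 had ratios of 0.67 and 0.64, and Nfil3 one of -0.60; against the local background column Nr1d1 was at -0.01 and Dbp at 0.99, below 2-fold. Male-biased liver genes had a median of 0.10, above nearly all random lists, with 10 of 16 higher (C6 0.86, C8b 0.67, Cyp7b1 0.49, Cyp4a12a 0.36), and no longer stood apart with plain subtraction, in the deposited values or against the local background column. Female-biased liver genes had a median of -0.02 within the random lists (Sult3a1 -0.85, Hao2 -0.68, Cyp3a44 0.65, Prom1 0.30), where Cyp3a44 had the opposite sign (-0.19) against that column. Erythroid and platelet markers had a median of 0.10, above 99.8% of random lists, with 10 of 12 higher; the globins Hbb-bt (0.50), Hbb-bs (0.42) and Hbb-b2 (0.23), near copies of each other, and Pf4 (0.33) were largest, with Pf4 at -0.01 against the local background column. This list no longer stood apart against the local background column, among genes at or above the median level or with the mean in place of the median. Markers of pancreas, fat and muscle had a median of -0.02 over 5 genes within the random lists (Cela1 -0.10, Plin1 -0.02, Ckm -0.02, Cela2a 0.02). A further 10 of these 20 markers were above background on neither array.

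The genes named for the largest lower ratios were 10 in number and mostly outside the lists. After Cyp4a14, they were the acetoacetyl-CoA synthetase Aacs (2.78-fold lower, deposited intensity 202 and 44), Pcp4l1 (2.42-fold), the hepcidin genes Hamp2 (2.28-fold, 8514 and 3413) and Hamp (2.02-fold, 12677 and 5842), Snx32 (2.27-fold), the first enzyme of haem synthesis Alas1 (2.14-fold, 2396 and 1039), the tubulin Tubb2a (2.04-fold), Thrsp and Uri1 (2.01-fold). Hamp and Hamp2 are near copies whose signals a probe may share. Against the local background column Aacs (-0.48), Pcp4l1 (-0.62) and Alas1 (-0.50) were below 2-fold and Uri1 had the opposite sign (1.11). Of genes above background on 1 array only, 464 were on the CKO array and 479 on the control array. The largest bounds on the lower side were those of 1700016H13Rik (at least 1.26-fold), Calb1 (1.20), the interleukin-7 receptor Il7r (1.18), Sstr4 (1.17) and Utf1 (1.17).

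**Figure D2:**
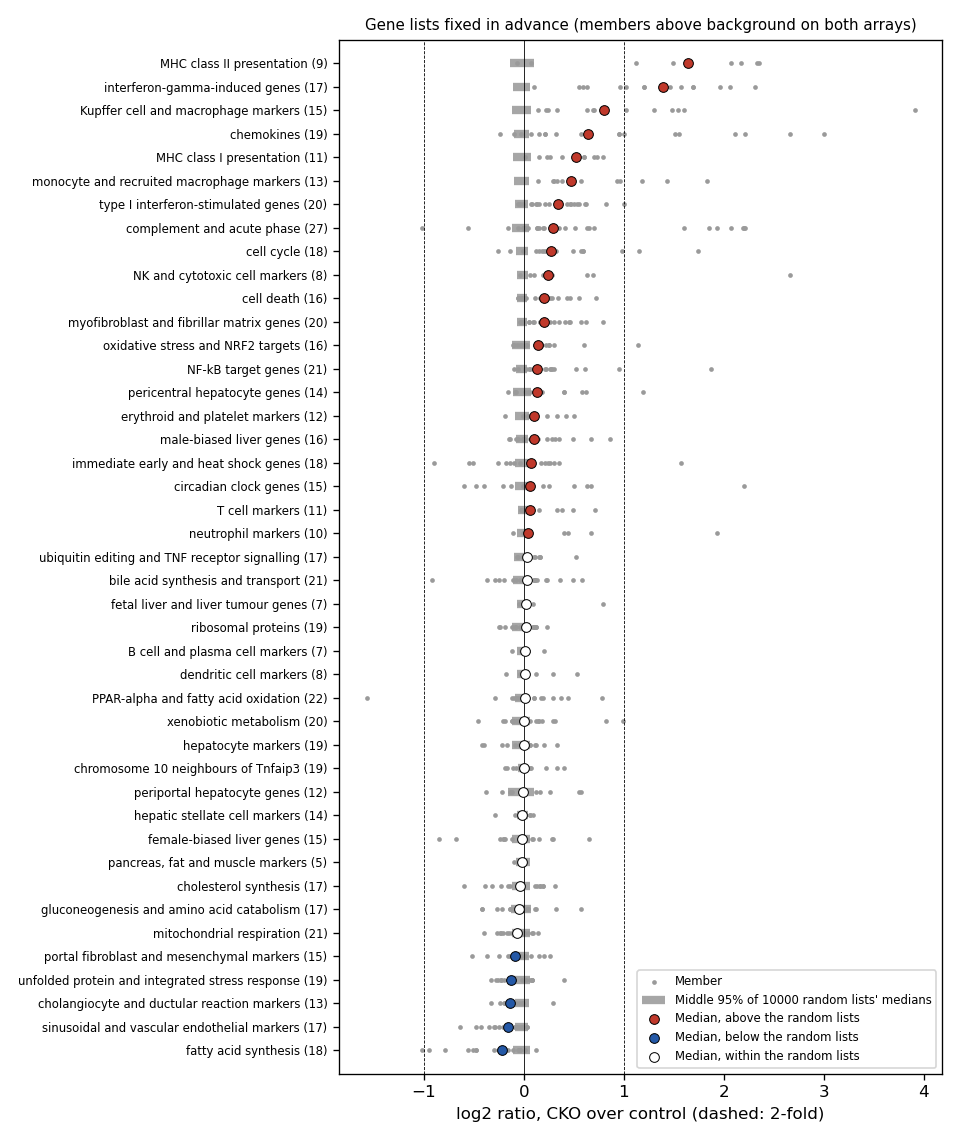
Log2 ratios, CKO over control, of the 43 gene lists, ordered by median; grey points are genes above background on both arrays (their number in brackets), grey bars span the middle 95% of the medians of 10000 random lists, and coloured points mark medians above (red), below (blue) or within (white) that range. The medians reach from -0.22 for fatty acid synthesis to 1.64 for MHC class II presentation, with 21 lists above and 5 below the range, where about 2.15 of 43 lists would fall outside by chance.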

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

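No paired analysis was possible because each genotype had 1 array, and for the same reason no array could be left out in turn. All 90 genes 2-fold higher and 11 genes 2-fold lower were past 2-fold in the same direction in the deposited values, and 90 and 10 of them with plain subtraction. Neither setting has an offset, and the offset shrinks ratios, so this overlap follows largely by construction and is no check of the calls. The counts themselves were larger: 181 higher and 19 lower with an offset of 16, as a smaller offset implies by construction for dim genes, and 608 and 44 with plain subtraction, which drops both normexp and the offset. They were 557 and 158 in the deposited values, which differ in scaling and rounding too. Against the local background column, the setting of the original design that became an alternative once the column had been examined, 432 genes were higher and 196 lower, 33 of the 90 and 7 of the 11 kept their side of 2-fold, and Tnfaip3 had a ratio of -0.20. Of the 176 named genes other than Tnfaip3, 143 moved by more than the spread of genes at their level. In that setting 12 lists stood apart as higher and 0 as lower, and 36 of 177 named genes had the opposite sign, 31 of them with a ratio beyond the spread in the chosen setting. Among named genes past 2-fold, the sign turned for Uri1 (1.11) and Rhbg (-0.93). Genes past 2-fold that are not named were not checked for a turn of sign. Among lists standing apart, it turned for cell death genes (-0.005), immediate early and heat shock genes (-0.021) and the unfolded protein response (0.046). Lists standing apart as lower numbered 3 with plain subtraction, 3 with the offset of 16, 3 in the deposited values, 3 among genes at or above the median level and 3 with the mean in place of the median. Immediate early and heat shock genes had a median of -0.065 among genes at or above the median level. Calls were gained by gluconeogenesis and ribosomal genes against the local background column, dendritic cell markers without a filter, fetal liver genes with the mean, and bile acid and mitochondrial genes with unmatched random lists. The other settings turned the sign of 4 named genes with plain subtraction and of 1 in the deposited values. The cause was not tested for these changes other than the counts with an offset of 16. Over the 8 settings for background, offset, scaling and source of values, the main one included, the interferon-gamma, MHC class II and Kupffer cell lists stayed at percentile 99.49 or higher of random lists. T cell markers gave no value among genes at or above the median level. In every setting 9 lists stood apart as higher and 0 as lower. Signal over background limits all of this most for genes near the blank spots.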

Other observations

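The tests of hepatocyte share, lymphoid tissue, animals and a fasted state, and the summaries by symbol family, were chosen after the results had been seen; the test of sampling time was fixed before its result was seen. Also set afterwards were the rules that dim markers, or lists whose members go both ways, leave an explanation open.

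Grouping genes by the letters of their symbols gave 438 families of at least 5 measured genes, of which 32 had medians above and 24 below the middle 95% of random lists, against 21.9 expected by chance. All 10 guanylate-binding protein genes (Gbp) were higher in the CKO liver, 6 of them by at least 2-fold, with a median log2 ratio of 1.16. All 12 interferon-inducible Ifi genes (median 0.32) and all 7 Toll-like receptors (median 0.17) were higher, and the medians of these 3 families were above 0 under each of 10 alternatives. The Toll-like receptors were dim, with median deposited intensities of 6 and 10, and their lowest median under the alternatives was 0.03. All 10 Parp genes were higher (median 0.19), with a median of -0.08 against the local background column. Immunoglobulin kappa variable genes (Igkv) were dim, with median deposited intensities of 9 and 11, and 11 of 12 were higher (median 0.10; 0.62 with plain subtraction). On the lower side, 14 of 15 Ndufa genes, which encode subunits of respiratory complex I, had lower values (median -0.14), as did 12 of 14 Sox genes (median -0.13), with the same sign under each of 10 alternatives. The Ndufa median lay at percentile 1.91 of random lists, while the mitochondrial respiration list fixed in advance, which holds Ndufa genes too, lay at 23.2 and did not stand apart.

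Within the acute phase list 5 of 27 genes were lower in the CKO liver, Hamp and Socs3 among them. Socs3, a feedback inhibitor of cytokine signalling chosen here after its value was seen, had a log2 ratio of -0.56 (deposited intensity 1283 and 816), and Hamp had one of -1.02.

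Interferon-gamma-induced, MHC class II and macrophage genes were higher together in the CKO liver. A lower share of hepatocytes, acting alone, would raise the markers of all other cell types alike. The Kupffer cell and macrophage median exceeded the endothelial median by 0.96 (SD 0.06 between matched random lists), which argues against such an even rise. Both medians were known when this comparison was chosen, and a lower share combined with other changes was not tested. More or activated macrophages stay possible. A piece of lymphoid tissue in the CKO sample cannot be told apart from a change in the liver itself: B cell and plasma cell markers lay at percentile 85.91 of random lists, but 2 of the 7 were at or above the median level of all genes, and T cell and Igkv genes were higher. A difference between the animals unrelated to genotype cannot be told apart from genotype either, since there was 1 array per genotype. An effect of genotype stays among the open explanations, as untested.

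Clock genes mostly differed in a way that follows their daily phase. The output genes had a median ratio of 0.38 over 8 genes (Dbp, Tef, Hlf, Nr1d1, Nr1d2, Per1, Per3 and Usp2), and those of the opposite phase had one of -0.39 over 5 (Arntl, Clock, Npas2, Nfil3 and Cry1). The difference of 0.77 (SD 0.08 between matched random lists) is what a different time of day at sampling could give. It exceeded 2 SD under each of 10 alternatives, at 0.20 to 1.75. The lowest, against the local background column, came mainly from the opposite-phase genes (median -0.18), with the output median at 0.02. On the offset scale Hlf, an output gene, was lower (-0.12), and Per1 (0.07) and Npas2 (-0.006) were near equal. An effect of genotype on the clock or on feeding times was not tested. Genes that cycle daily in liver, including those of lipid synthesis, may differ between the livers for this reason.

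Fatty acid synthesis genes were lower, with a median of -0.22. A fasted state of the CKO mice could lower them, and would raise genes of fatty acid oxidation and gluconeogenesis. These lists lay at percentiles 85.12 and 41.52 of random lists with members on both sides (12 of 22 and 7 of 17 higher), and at 70.2 and 98.0 against the local background column, so a fasted state cannot be told apart from an effect of genotype: Plin2 and Pck1 were higher and Cyp4a14 lower. Sampling time, for which clock genes differed by 0.77, stays open for this list too.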
